A study of Mus musculus with 8 samples.

How the data were processed

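The series holds 8 libraries of mouse 2-cell embryos, 4 after injection of a scrambled morpholino and 4 after injection of a Med13 morpholino. Per the labels' protocols, total RNA came from 4 independent collections of 40 embryos per group, was amplified with the Ovation RNA-Seq System V2, and went into TruSeq libraries from 400 ng of cDNA. The replicates are therefore separate collections, and p-values measure the spread between collections.

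The authors deposited 1 table of FPKM values (fragments per transcript length and library total) with 97496 rows, each an Ensembl transcript with its gene symbol, for 38406 symbols. Per the submitters' processing notes, reads were handled with BWA and the mm10 build. The BWA version, the counting tool, the annotation release and the strand setting are not given in the sources used here. Columns were matched to samples by the number in each title, and 0 columns were left unmatched. Of the rows, 96224 (98.7%) matched a transcript of GENCODE M21 (GRCm38, the same assembly as mm10), which gave lengths, GC content, biotypes and coordinates.

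In 3758 rows, which are exactly those whose symbol holds a hyphen, the values are moved by 1 column: text stands in the column of scrambled replicate 1, and Med13 morpholino replicate 4 has no value. In these rows, 3232 values equalled 1 or 2 fragment steps of the library on the left, 0 those of their own column and 1 those of another library. The rows hold 3430 symbols, all mitochondrially encoded genes among them, and were left out of the main comparison, so the fixed list of mitochondrially encoded genes had 0 measured members. The remaining 93738 rows gave 34976 symbols. The unit was treated as FPKM in all 8 columns.

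Multiplied by transcript length, low values came out as multiples of a step of 0.5 fragments. Within 0.005 fragments, 94.3% to 94.5% of the values of up to 20 fragments were such multiples, and the step gave back a whole library total per sample, 31378977 to 48050262 fragments. Isoforms of a gene share exons, and how the authors assigned a fragment to several isoforms is not given in the sources used here, so a summed FPKM may count a fragment more than once. The totals bound precision for low genes, and the amplified reads carry no molecular identifiers.

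Rows sharing a symbol were summed, and genes with a mean FPKM of at least 1 over the 8 libraries were kept, 11755 in all. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean-variance trend, two-sided, no covariate, Benjamini-Hochberg adjusted p below 0.05). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The Med13 level was tested by an exact permutation test over 70 assignments. Gene lists were fixed before the data were examined: lists with at least 5 measured members (28) were tested with camera at a preset correlation of 0.01, and camera with an estimated correlation and fry were run beside it, with Benjamini-Hochberg adjustment over lists. Means of each list per library were compared by exact permutation, a test added after the data were seen. Its smallest possible p is 0.0286. After adjustment over 28 lists it could fall below 0.05 only if many lists reached that minimum together. The fixed lists covered the Mediator kinase module and core, RNA polymerase II, 2-cell-specific, Obox, embryonic transcription factor, oocyte, heat shock, ribosome, translation, splicing, proteasome, energy, chromatin, cell cycle, p53, apoptosis, stress, interferon, transport and decay genes, housekeeping and histone controls, and markers of cumulus, sperm, blood, immune and oviduct cells and of later stages. The 8 libraries divide into 4 and 4 in 35 ways, the real grouping included.

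Genes were named by a rule fixed in advance: the Mediator kinase module; the 10 largest rises and falls among called genes whose groups did not overlap and whose symbols were not clone or predicted names; and up to 4 members of each list, those with the smallest adjusted p, filled to 2 with the most abundant members. Dppa3, Ddx4, Pou5f1, H2-Aa, Hba-a1 and Hba-a2 were named after their values were seen, the last 3 in the realigned rows only. Among the 127 genes under the rule, 5 share over 20% of their exonic bases with another gene, Bad, Hist1h1e, Itgam, Mpc1 and Ovgp1, and Txnip shares 19.4% with an antisense gene, so their values may include reads of a neighbour.

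Before use, the scripts were tested on simulated data for this comparison, with 200 changed genes among 11755. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2. The scripts recovered 2% of genes changed by 0.5 on the log2 scale, 68% at 1, and 100% at 2 and at 3, and 6.2% of calls were unchanged genes. The real comparison called 2010 genes, which eases the adjusted p threshold, so these rates do not carry over to it. Of 28 simulated lists, the 1 moved list was called and 0 others. Since the simulated genes varied independently, this says nothing about false calls when the genes of a list vary together.

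Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, median-ratio, quantile and equal-sum scaling, limma without the trend, robust or with sample weights, a block by consecutive title numbers, leaving out each library, an adjusted p below 0.1, and transcripts kept apart. Added after the data were seen were protein-coding transcripts only, the main transcript only, voom on fragments read back from the steps, realigned rows with 7 libraries, and removal of GC and length trends (99.1% of tested genes had both). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.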

Results

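RNA levels were measured in late 2-cell embryos of CF-1 mice, an outbred stock. Early 1-cell embryos had been injected with a scrambled morpholino or with a morpholino directed at Med13, and each library was made from a pool of 40 embryos. Morpholinos are antisense oligomers that bind a target RNA and block its translation or splicing. Each group had 4 independent collections, which gave 8 libraries in all, and the deposited values were FPKM per transcript. The library totals behind the FPKM, read back from the values, were 37680249, 42996188, 48050262 and 33541914 fragments for scrambled replicates 1 to 4 and 37775901, 40023015, 31378977 and 45748802 fragments for Med13 morpholino replicates 1 to 4. By the title of the series, the comparison asks how MED13, a subunit of the kinase module of the Mediator complex, bears on activation of the zygotic genome.

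The targeted mRNA did not differ detectably between the groups. Med13 (ENSMUSG00000034297, GRCm38 chromosome 11, 86267033 to 86357602, minus strand) had a summed FPKM over its 4 exonic transcript models of 41.3 ± 4.31 (SD, n = 4) in scrambled controls and 42.2 ± 2.14 (SD, n = 4) after Med13 morpholino. The log2 difference was 0.03 (two-sided exact permutation p = 0.629 over 70 assignments, where the smallest possible p is 0.0286), and the 95% interval from limma ran from a fold of 0.82 to 1.27. The protein-coding model of 10546 bases had an FPKM of 21.6 ± 1.17 and 22.2 ± 0.586 (SD, n = 4 each). A morpholino can block translation and leave its target mRNA in place, so this level does not test the labels, and MED13 protein was not measured here. None of the 7 measured genes of the Mediator kinase module passed the test in the main fit (0 adjusted over the list alone; camera adjusted p = 0.495). Cdk8, the kinase itself, came nearest, with 44.4 ± 5.33 FPKM in controls and 60.6 ± 4.47 after Med13 morpholino (SD, n = 4 each; log2 fold change 0.45 ± 0.15 SE, limma adjusted p = 0.0634). Settings in which Cdk8 passed included median-ratio scaling (limma adjusted p = 0.0242), quantile normalization (0.0283), sample weights (0.0437) and protein-coding transcripts only (0.0413). The main transcript only (0.0491), voom (0.0461) and GC and length trends removed (0.023) were others.

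**Figure D1:**
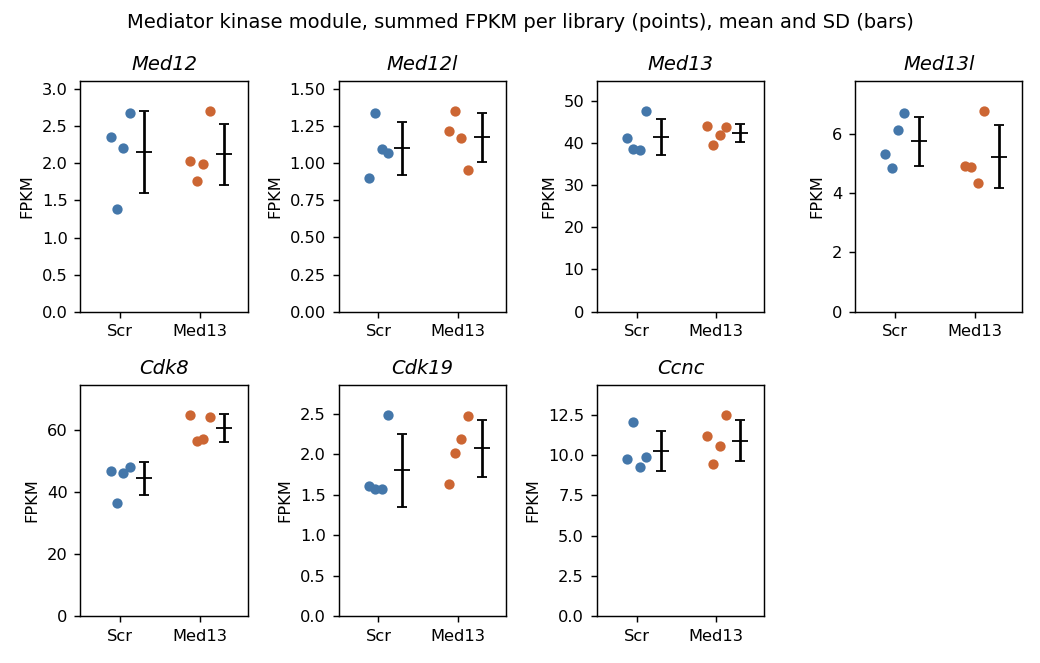
Summed FPKM (y axis) of the 7 genes of the Mediator kinase module in each of the 8 libraries (points; blue for scrambled morpholino, orange for Med13 morpholino), with the group mean and SD (n = 4) as bars. Med13 lies at means of 41.3 and 42.2 FPKM, and Cdk8 at 44.4 and 60.6 FPKM.

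The largest rises after Med13 morpholino were in Gyg, the glycogenin that primes glycogen synthesis, and in Tle6, a member of the subcortical maternal complex of eggs and early embryos. Gyg (GRCm38 chromosome 3, 20122084 to 20155317) went from 10.04 ± 1.502 to 163 ± 22.4 FPKM (SD, n = 4 each; log2 fold change 3.89 ± 0.17 SE, limma adjusted p = 1.13e-07). Tle6 (chromosome 10, 81590904 to 81601073) went from 4.22 ± 0.486 to 44.2 ± 9.86 FPKM (log2 fold change 3.09 ± 0.18 SE, adjusted p = 1.31e-06). The 8 next largest rises among genes whose groups did not overlap were in Txnip (3.08), an inhibitor of thioredoxin, Tmem232 (2.88), Iqca (2.57), Pla2g4c (2.56), the mitochondrial deubiquitinase Usp30 (2.36), Pkd2l2 (2.29), Fam217a (2.28) and Oosp1 (2.27), an oocyte-secreted protein, as log2 fold changes. The largest falls were in the transcription factor Sox15, from 19.5 ± 10.3 to 3.50 ± 1.63 FPKM (log2 fold change -2.10 ± 0.35 SE, adjusted p = 0.0026), and in Fam208a, which encodes the HUSH silencing subunit TASOR, from 17.6 ± 1.30 to 4.23 ± 0.755 FPKM (log2 fold change -1.84 ± 0.16 SE, adjusted p = 3.51e-05). Falls followed in the actin-binding Pfn1 (-1.83), the nuclear noncoding RNA Malat1 (-1.78), the replication helicase factor Cdc45 (-1.69), the mitochondrial chaperone Clpx (-1.64), Adgrl3 (-1.62), the antiproliferative Tob1 (-1.62), the acyl-CoA synthetase Acsl4 (-1.53) and the microRNA locus Mir5099 (-1.48).

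Of 11755 genes with a mean FPKM of at least 1, limma called 2010 as changed, 1092 higher and 918 lower after Med13 morpholino. Changes of at least 2-fold were more often rises, with 316 higher and 110 lower. The groups did not overlap in 2535 genes (21.6%), where chance gives 2.9% on average. Genes vary together, so by chance the share in 1 division of the libraries can lie far from that average. The count fell to 1113 without scrambled replicate 3, to 1291, 956 and 1245 without Med13 morpholino replicates 1, 2 and 3, and to 1012 with no filter on low values, and it rose to 4336 with sample weights. Without scrambled replicate 2, 43.7% of the calls were higher against 54.3% with all libraries, and with sample weights 39.5% were.

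**Figure D2:**
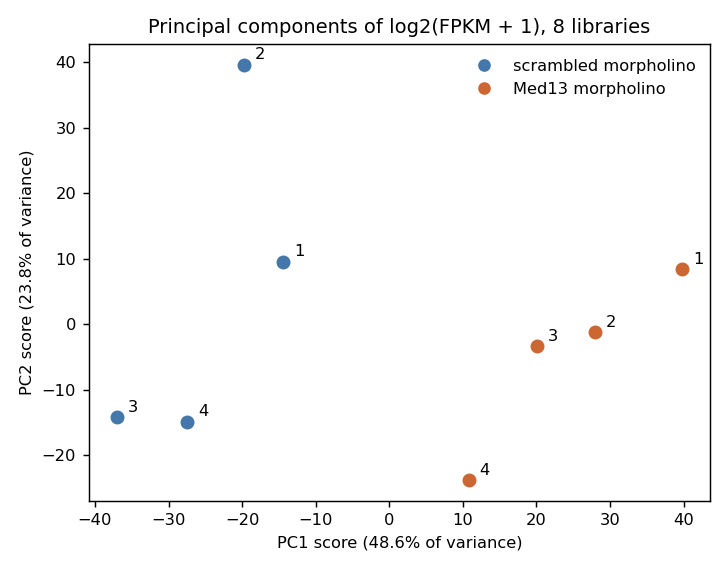
Scores of the 8 libraries on principal components 1 (x axis, 48.6% of variance) and 2 (y axis, 23.8%) of log2(FPKM + 1) over 11755 genes. Points are numbered by replicate; scrambled libraries (blue) lie between -37 and -14.4 and Med13 morpholino libraries (orange) between 10.8 and 39.8 on component 1, and scrambled replicate 2 lies apart at 39.6 on component 2.

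The libraries parted by group along the first principal component, which held 48.6% of the variance. The mean Pearson correlation across genes was 0.966 within groups and 0.929 between them. Scrambled replicate 2 stood apart on the second component, and 20.8% of its summed FPKM came from its 10 most abundant genes, against 13% to 13.8% in the other scrambled libraries and 16.4% to 17.5% in the Med13 morpholino libraries.

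Transcripts of the oocyte were higher after Med13 morpholino. Of 79 measured oocyte and maternal-effect genes, 34 rose and 1 fell (43 and 2 adjusted over the list alone), with a median log2 fold change of 0.51. Bmp15 and Gdf9, the growth factors that oocytes secrete, went from 15.6 ± 0.756 to 70.8 ± 11.4 FPKM and from 15.2 ± 2.70 to 64.7 ± 9.74 FPKM (SD, n = 4 each; log2 fold changes 2.10 ± 0.16 and 2.02 ± 0.17 SE, limma adjusted p = 1.41e-05 and 3.72e-05). Oosp1 went from 39.0 ± 7.67 to 189 ± 16.4 FPKM. The rises were uneven within the list: Dppa3, named after its value was seen, stood at 558 ± 58.2 and 536 ± 119 FPKM, and the germ cell helicase Ddx4, also named after its value was seen, was the member that fell (log2 fold change -0.65), a call lost without Med13 morpholino replicate 2 (limma adjusted p = 0.0588). The list was called by camera with a preset correlation (adjusted p = 2.55e-14) and by fry (adjusted p = 0.0199), and not with an estimated correlation (adjusted p = 0.938). Its mean lay higher in all 4 Med13 morpholino libraries than in any scrambled library (difference in mean log2 0.62, exact permutation p = 0.0286, the smallest possible, and 0.266 after Benjamini-Hochberg adjustment over 28 lists).

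Genes expressed transiently at the 2-cell stage were also higher. Of 59 measured 2-cell-specific genes, 27 rose and 1 fell (37 and 2 adjusted over the list alone), with a median log2 fold change of 0.74. The zinc finger gene Zfp352 went from 38.7 ± 10.9 to 123 ± 26.4 FPKM (SD, n = 4 each; log2 fold change 1.66 ± 0.24 SE, limma adjusted p = 0.00101) and Tmem92 from 58.7 ± 11.5 to 129 ± 22.7 FPKM (log2 fold change 1.13 ± 0.19 SE, adjusted p = 0.00281). Tdpoz3 and Tdpoz5 rose with log2 fold changes of 1.89 and 1.00. The one member that fell was the initiation factor Eif1a (log2 fold change -0.63). Tdpoz, Obox, Zscan4, Pramef and Usp17l genes have near-identical copies that can share reads, so values of single members are uncertain. Shared reads can also count 1 change in several members. The count of rises and the camera p at the preset correlation of 0.01 may therefore be overstated in strength. The list was called by camera with the preset correlation (adjusted p = 1.52e-12) and not with an estimated correlation (adjusted p = 0.938) or by fry (adjusted p = 0.0836). Its mean was higher by 0.78 on the log2 scale (exact permutation p = 0.0571), above every scrambled library in 3 of the 4 Med13 morpholino libraries. Of 7 measured Obox homeobox genes, 2 rose (2 adjusted over the list alone), Obox1 and Obox3 (log2 fold changes 0.79 and 0.80), and camera did not call the list (adjusted p = 0.137). Its mean lay higher in all 4 Med13 morpholino libraries than in any scrambled library (difference 0.329, exact permutation p = 0.0286, and 0.266 adjusted over 28 lists). The Obox1 call was lost without Med13 morpholino replicate 2 (limma adjusted p = 0.0506), and the Obox3 call in 6 of the 8 fits that left out 1 library (up to 0.135).

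Several regulators that embryos switch on were lower. Of 28 measured embryonic transcription factors, 7 fell and 1 rose (7 and 2 adjusted over the list alone), with a median log2 fold change of -0.30. Dppa2, an activator of the 2-cell program, went from 84.1 ± 15.7 to 44.6 ± 6.46 FPKM (SD, n = 4 each; log2 fold change -0.89 ± 0.18 SE, limma adjusted p = 0.0059). Tead4, which specifies trophectoderm, went from 24.1 ± 5.82 to 12.1 ± 2.47 FPKM, Nr5a2 from 46.2 ± 7.53 to 25.7 ± 6.85 FPKM and Yy1 from 63.6 ± 34.2 to 24.1 ± 3.02 FPKM. The member that rose was the pluripotency factor Pou5f1, named after its value was seen, from 2.07 ± 1.14 to 4.35 ± 0.728 FPKM, a call lost with no filter and without scrambled replicate 3 or Med13 morpholino replicates 1 or 2 (limma adjusted p = 0.0957, 0.0684, 0.0702 and 0.0502). Camera did not call the list (adjusted p = 0.167). Its mean was lower by 0.245 (exact permutation p = 0.0571, and 0.266 adjusted over 28 lists). Of 7 measured trophectoderm and inner cell mass markers of later stages, 1 fell (1 adjusted over the list alone; camera adjusted p = 0.292). It was Nanog, from 4.69 ± 0.544 to 2.83 ± 0.382 FPKM (log2 fold change -0.57 ± 0.15 SE, limma adjusted p = 0.0205). Gata4 of the same list stood at 21.8 ± 6.34 and 26.6 ± 2.67 FPKM. The mean of this list lay lower in all 4 Med13 morpholino libraries than in any scrambled library (difference -0.339, exact permutation p = 0.0286, and 0.266 adjusted). Without scrambled replicate 3 or Med13 morpholino replicate 2 the calls of Nr5a2 and Nanog were lost, and that of Nanog also without Med13 morpholino replicate 3 (limma adjusted p up to 0.0537 and 0.0692).

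**Figure D3:**
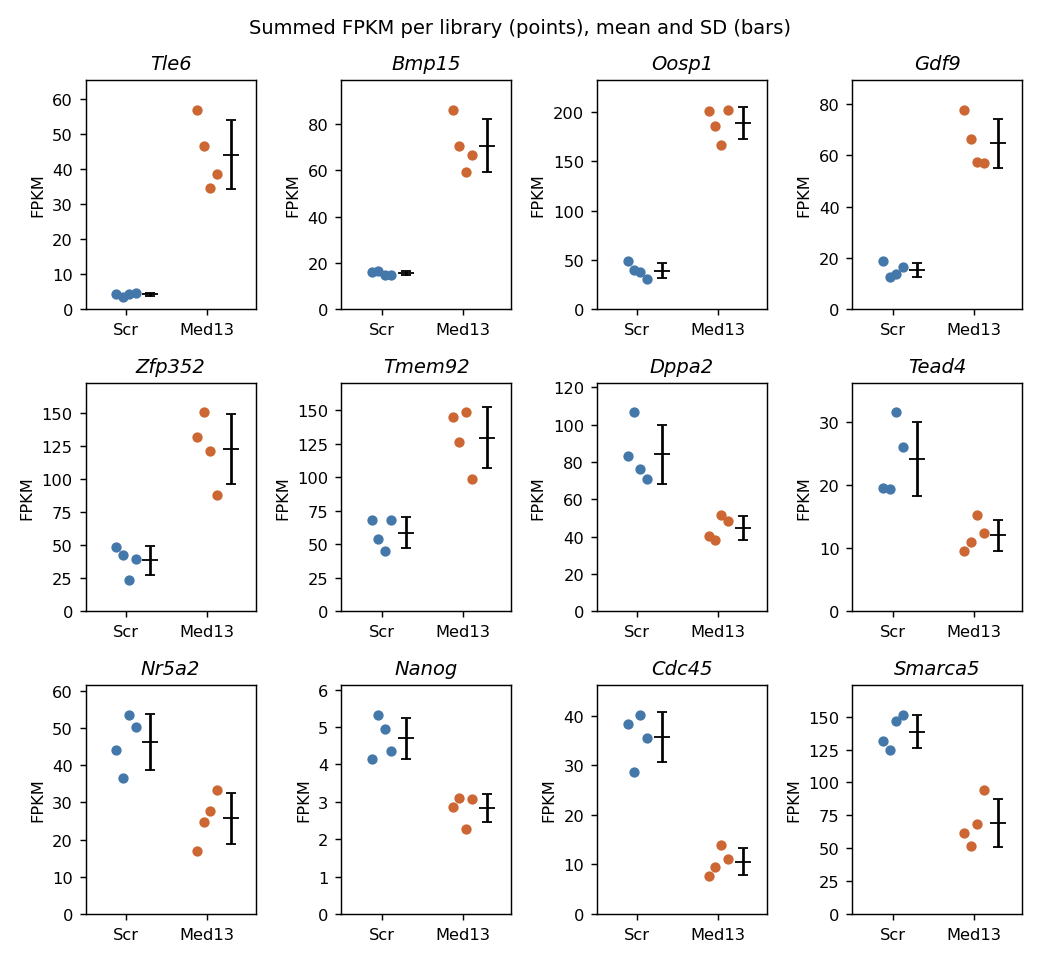
Summed FPKM (y axis, from 0) of 12 genes in each of the 8 libraries (points; blue for scrambled morpholino, orange for Med13 morpholino), with group mean and SD (n = 4) as bars. All 4 Med13 morpholino libraries lie above all scrambled libraries for Tle6, Bmp15, Oosp1, Gdf9, Zfp352 and Tmem92, and below them for Dppa2, Tead4, Nr5a2, Nanog, Cdc45 and Smarca5.

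Genes for protein synthesis and RNA processing leaned lower in their medians. Among all 11755 genes tested, 918 fell and 1092 rose, a share of falls close to that in the translation and ribosome biogenesis lists. Of 48 translation factors, 4 fell and none rose (3 and 0 adjusted over the list alone), namely Eef1e1, Eif5b, Eif1a and Eif1ax (log2 fold changes -0.89, -0.80, -0.63 and -0.53). Of 95 splicing genes, 12 fell and none rose (4 and 0 adjusted over the list alone), among them the helicase Dhx15 (-0.83), the U6 RNA binding Lsm2 (-0.80), Srsf6 (-0.93) and the branch point factor Sf3b1 (-0.63). Of 116 ribosome biogenesis genes, 8 fell, such as the GTPases Gnl2 (-1.09) and Gnl3l (-0.65), and 3 rose, such as Nop10 (1.05) and Riok1 (0.87), with the same counts adjusted over the list alone. Camera called all 3 lists with the preset correlation (adjusted p = 0.00828, 0.0258 and 0.0258 in that order) and none with an estimated correlation (adjusted p = 0.938 each) or by fry (adjusted p = 0.405, 0.414 and 0.55). Their mean deviations were -0.51, -0.43 and -0.49 in Med13 morpholino replicate 1 and 0.18, 0.19 and 0.20 in replicate 4. Without replicate 1 no call held (camera adjusted p = 0.174, 0.23 and 0.361), nor did any with the main transcript only (0.0509, 0.1005 and 0.1005). The splicing call was also lost without scrambled replicate 2 (0.0942), with a median log2 fold change of -0.263 against -0.224 in the main fit. The ribosome biogenesis call was lost without scrambled replicate 3 (0.0882; median -0.124 against -0.204). Both were lost with quantile normalization (0.0753 and 0.0601) and at a mean FPKM of at least 5 (0.0575 each). In all these fits the medians stayed below 0, from -0.268 to -0.078, where protein-coding genes had a median of -0.058 in the main fit. Of 82 cytosolic ribosomal proteins, 1 fell (0 adjusted over the list alone; camera adjusted p = 0.292), Rps29, from 345 ± 37.9 to 208 ± 55.2 FPKM, and Rplp2 stood at 353 ± 40.8 and 410 ± 121 FPKM (SD, n = 4 each). Its median log2 fold change of -0.127 turned to 0.092 without Med13 morpholino replicate 1 (camera adjusted p = 0.23), and without replicate 4 it was -0.287 and the list was called (0.00148). In that last fit the translation, splicing and ribosome biogenesis calls held, with larger falls in their medians (-0.396, -0.317 and -0.317). Without Med13 morpholino replicate 2, limma no longer called Eef1e1, Eif5b, Eif1a, Eif1ax, Srsf6, Sf3b1, Gnl3l and Rps29, and over the fits that left out 1 library their adjusted p reached 0.135.

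Called genes of the transcription machinery and of chromatin went in both directions. Their shares of each list were near the share over all genes tested (2010 of 11755). In core Mediator, 3 of 26 genes rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.434): Med15, Med26 and Med11 were higher (log2 fold changes 0.83, 0.91 and 0.71) and the scaffold Med14 lower (-0.55). Among 59 genes of RNA polymerase II and its general factors, 4 rose and 5 fell (the same adjusted over the list alone; camera adjusted p = 0.776), with Gtf2f2 (1.07) and Polr2g (1.08) higher and the elongation factors Tcea1 (-1.06) and Ell2 (-0.64) lower. Tcea1 went from 93.7 ± 8.31 to 44.4 ± 4.58 FPKM (SD, n = 4 each; limma adjusted p = 0.00103). Of 47 chromatin remodelling genes, 3 rose and 5 fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.304). Smarca5, the ISWI ATPase, went from 139 ± 12.6 to 69.0 ± 18.2 FPKM (limma adjusted p = 0.00447) and its partner Baz1a from 94.0 ± 9.20 to 59.8 ± 3.15 FPKM, and Chd4 (0.80) and Arid1b (0.67) were higher. Of 76 histone-modifying enzymes, 5 rose and 8 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.287). The dioxygenase Tet3, which oxidises methylcytosine in zygotes, and the corepressor Sin3a were higher (1.46 and 1.49), and the corepressor Rcor1 and the H3K9 demethylase Kdm3a lower (-0.93 and -1.45). Leaving out 1 library ended the call of Med14 in 5 of 8 fits, of Baz1a and Arid1b in 2, and of Med11 and Ell2 in 1 (limma adjusted p up to 0.0899).

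**Figure D4:**
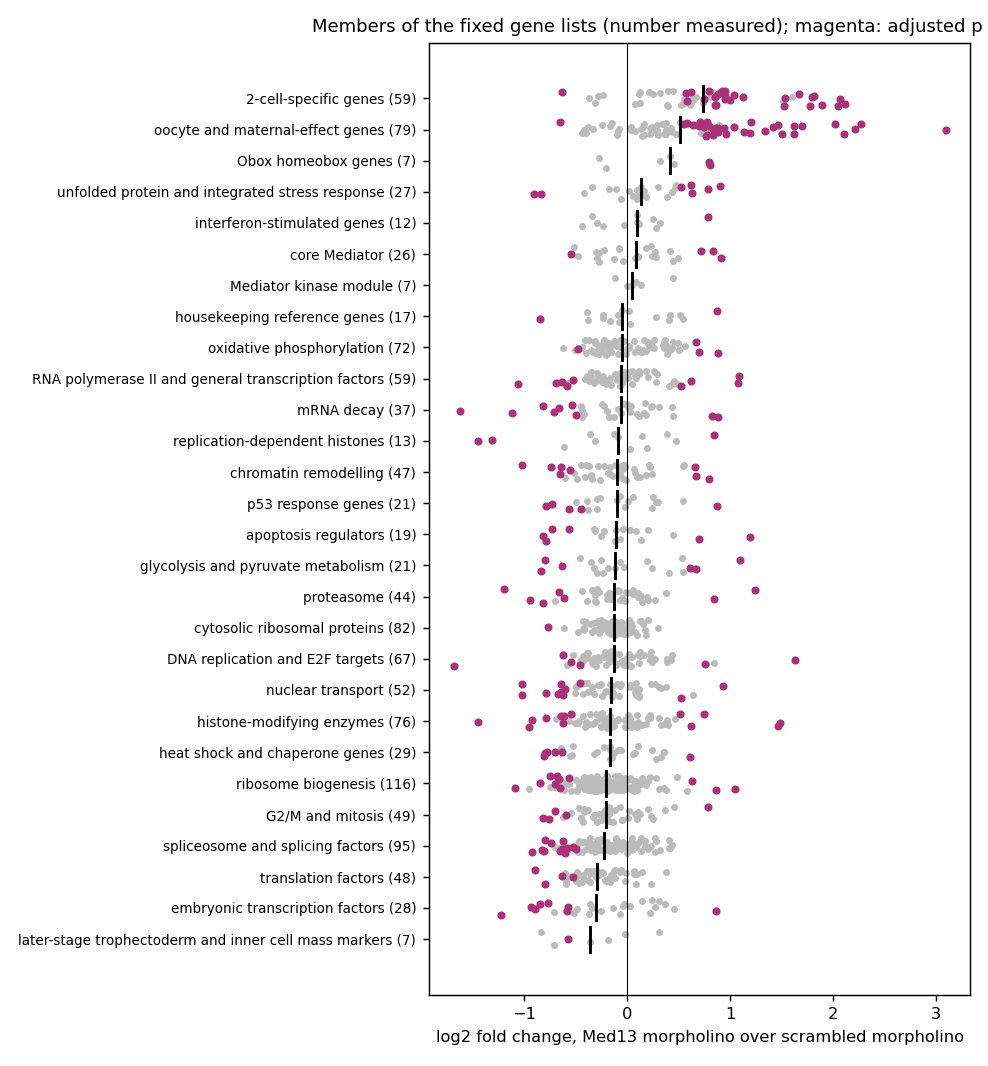
Log2 fold change of Med13 morpholino over scrambled morpholino (x axis) for each measured member (points) of the 28 lists with at least 5 measured members (y axis, ordered by median, number measured in brackets). Magenta points have a limma adjusted p below 0.05, and black bars mark list medians, which run from -0.36 for the later-stage markers to 0.74 for 2-cell-specific genes.

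Cell cycle genes held single strong changes in lists that camera did not call. The called share was below that of all genes tested (2010 of 11755) in the replication and mitotic lists. It was above that in the p53 and apoptosis lists. Among 67 replication genes and E2F targets, 2 rose and 4 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.374). The origin factor Orc5 went from 3.98 ± 0.505 to 14.4 ± 1.68 FPKM (SD, n = 4 each; limma adjusted p = 5.12e-05), E2f2 rose (0.76), and Cdc45 and Mcm10 were lower (-1.69 and -0.63). Among 49 mitotic genes, 1 rose and 4 fell (the same adjusted over the list alone; camera adjusted p = 0.107), with the phosphatase Cdc25b higher (0.79) and the kinase Aurka (-0.81), the condensin Smc4 (-0.70) and Spc24 (-0.60) lower. The p53 response list had 1 of 21 genes higher, Ercc5 (0.87), and 4 lower (the same adjusted over the list alone; camera adjusted p = 0.458), including Apaf1 (-0.79), Trp53inp1 (-0.56) and Bax (-0.73). Among 19 apoptosis regulators, 2 rose and 4 fell (the same adjusted over the list alone; camera adjusted p = 0.568). Bcl2l10, an oocyte member of the Bcl2 family, was higher (1.19) and the death promoting Bad lower (-0.82). Cflar was higher on the summed transcripts (0.69) and lower when protein-coding transcripts alone were summed (-0.56). Leaving out 1 library ended the calls of Mcm10, Smc4, Spc24, Trp53inp1 and Bax in 4 to 7 of 8 fits (limma adjusted p up to 0.144).

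Camera called none of the stress, mRNA decay and nuclear transport lists. Of 27 genes of the unfolded protein and integrated stress responses, 5 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.107), with Calr (0.90), Pdia4 (0.78) and Manf (0.62) higher and Dnajb9 lower (-0.84). The mean of this list was higher by 0.14 (exact permutation p = 0.0571, and 0.266 adjusted over 28 lists). Of 29 heat shock and chaperone genes, 1 rose and 5 fell (the same adjusted over the list alone; camera adjusted p = 0.267), with Hsp90aa1 going from 227 ± 29.1 to 128 ± 10.2 FPKM (SD, n = 4 each; limma adjusted p = 0.0057) and Hsf2 (-0.70), Cct6a (-0.63) and Hspa4 (-0.80) lower. Among 12 interferon-stimulated genes, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.495), Ifit1, from 0.617 ± 0.224 to 1.79 ± 0.478 FPKM, and Stat2 stood at 6.51 ± 1.56 and 6.26 ± 1.10 FPKM. Among 37 mRNA decay genes, 2 rose and 7 fell (the same adjusted over the list alone; camera adjusted p = 0.333): the deadenylation factors Tob1 (-1.62) and Btg3 (-1.12) and the ARE-binding Zfp36l2 (-0.81) were lower and Patl1 higher (0.83). Of 52 nuclear transport genes, 2 rose and 9 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.116), with the importins Kpna4 (-1.02), Kpna6 (-0.67) and Tnpo1 (-0.64) and the nucleoporin Nup85 (-1.02) lower. Leaving out 1 library ended the call of Dnajb9 in 6 of 8 fits, of Hspa4 in 3, and of Hsf2, Cct6a, Zfp36l2 and Tnpo1 in 1 (limma adjusted p up to 0.092).

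Camera called none of the proteasome, energy, housekeeping and histone lists. In the proteasome, 2 of 44 genes rose and 5 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.304), with Psmf1 (1.24) and Psmb6 (0.84) higher and Psmg3 (-1.20) and Psma5 (-0.94) lower. In oxidative phosphorylation, 3 of 72 nuclear genes rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.806). Cox7b (0.88), Ndufa1 (0.70) and Ndufa2 (0.67) were higher and Uqcrfs1 lower (-0.48), and the list's median of -0.05 and mean of 0.01 differed in sign. Among 21 glycolysis and pyruvate genes, 3 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.806), with Gpi1 higher (1.10) and the pyruvate carrier Mpc1 (-0.84), the monocarboxylate transporter Slc16a1 (-0.80) and Ldha (-0.63) lower. Of the 17 housekeeping reference genes, 1 rose, Ywhaz (0.87), and 1 fell, Ubtf (-0.85) (the same adjusted over the list alone; camera adjusted p = 0.693), and the list's median of -0.05 and mean of 0.04 differed in sign. Of 13 replication-dependent histone genes, 1 rose, Hist1h1a (0.84), and 2 fell, Hist1h1e (-1.45) and Hist1h1b (-1.32) (the same adjusted over the list alone; camera adjusted p = 0.806). Values of linker histone genes are uncertain because related copies can share reads. Leaving out 1 library ended the calls of Ndufa1, Ndufa2, Uqcrfs1 and Ldha in 4 to 7 of 8 fits, and of Slc16a1, Ubtf and Hist1h1a in 1 or 2 (limma adjusted p up to 0.142).

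Most markers of other cells with unshifted rows stayed near the floor in both groups. The median FPKM of 30 cumulus and granulosa markers was at most 0.1 in every library, and 3 of them had a mean of at least 1, led by Serpine2 (14.2 ± 0.222 and 12.5 ± 1.77 FPKM, SD, n = 4 each) and Amhr2 (12.8 ± 2.82 and 13.4 ± 2.14 FPKM). Of 18 sperm and spermatid markers, 3 reached a mean of 1, among them Odf2 (9.50 ± 2.78 and 15.4 ± 3.13 FPKM, limma adjusted p = 0.0586) and Ldhc (2.84 ± 1.34 and 3.22 ± 0.595 FPKM). Settings in which Odf2 passed included median-ratio scaling, quantile normalization, protein-coding transcripts only and GC and length trends removed (limma adjusted p 0.0272 to 0.0462). None of the 5 blood cell markers did, and 2 of 16 immune cell markers did, Itgam (1.84 ± 0.494 and 1.37 ± 0.282 FPKM) and Cd68 (1.21 ± 1.04 and 0.842 ± 0.422 FPKM). Of 16 oviduct markers, 4 reached a mean of 1 and 1 fell (1 adjusted over the list alone, with 1 more higher), the oviduct glycoprotein gene Ovgp1 (3.49 ± 0.679 and 2.18 ± 0.189 FPKM, limma adjusted p = 0.044, lost in 7 of 8 fits that left out 1 library, up to 0.125). Epcam of this list stood at 23.5 ± 5.65 and 29.5 ± 3.44 FPKM. These counts leave out symbols with a hyphen. In the rows realigned in 7 libraries, the class II gene H2-Aa of the immune list was higher after Med13 morpholino (0.940 ± 0.460 and 4.375 ± 1.376 FPKM, SD, n = 4 and 3; limma adjusted p = 0.00231). The globin genes Hba-a1 (1.84 ± 0.545 and 3.015 ± 0.685 FPKM, adjusted p = 0.0931) and Hba-a2 (1.69 ± 0.850 and 3.04 ± 0.137 FPKM, adjusted p = 0.0796) were not called.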

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

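The tests of scaling, GC content and length, mixed samples, the single library, shifted columns and other splits were chosen after the results were seen, and the test of a shared course within groups before. A value standing far from the other 3 of its group is found by chance in about 5% of groups, and 16 of 324 groups of 4 had one.

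Among single genes, scrambled replicate 2 was the stray library for Cdk8 (36.5 FPKM, against 46.2 to 48.1 in the others), Hsf2 (6.51, against 4.19 to 4.48), Ifit1 (0.95, against 0.478 to 0.545) and Tnpo1 (21.5, against 27.1 to 27.9). Scrambled replicate 4 strayed for Cdk19 (2.48 FPKM, against 1.57 to 1.6) and Hsp90aa1 (183, against 236 to 245), and scrambled replicate 1 for Sf3b1 (51 FPKM, against 56.4 to 56.9). Clpx was highest in Med13 morpholino replicate 3 (17.1 FPKM, against 11.8 to 12.6), and Rps29 lowest in Med13 morpholino replicate 1 (126, against 230 to 246). Over the whole library, scrambled replicate 2 also strayed in its summed FPKM (216000, against 209000 to 210000) and in the share of its 10 most abundant genes (20.8%, against 13% to 13.8%). Its mean deviation was low for embryonic transcription factors (0.005, against 0.154 to 0.172), glycolysis genes (-0.214, against 0.062 to 0.106) and replication genes (-0.157, against 0.098 to 0.118). Med13 morpholino replicate 4 strayed upward for glycolysis genes (0.101, against -0.059 to -0.032) and mRNA decay genes (0.095, against -0.151 to -0.111).

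In the rows moved by 1 column, which the main comparison leaves out, the 2 largest called rises among genes with ordinary symbols, once realigned in 7 libraries, were those of the class II gene H2-Aa (log2 fold change 1.47) and Ighv1-60 (1.45).

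Of 35 splits of the 8 libraries only 1, the real one, gave 2010 changed genes, and the highest other gave 0. Every other split mixes the groups, so a real group difference widens its spread and holds its count down. The real split could stand out no further than 1 of 35, so this argues against chance division and does not exclude it. The number of lists called by camera gives no such argument, since 24 of the 35 splits called at least 5 lists and the highest other called 15.

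The higher oocyte transcripts, the first pattern weighed, kept a median log2 fold change of at least 0.487 over 3 scalings. Median-ratio, quantile and equal-sum scaling moved the median gene by only 0.036, 0.004 and -0.025. They could therefore hardly bring the list's median of 0.511 to 0. All 3 set the libraries to a common level, so a change in total RNA per embryo was not tested. GC content and length were argued against: 35 members were higher with those trends removed, against 34 before. Unfertilised eggs or arrested 1-cell embryos in the pools stay open: they would lower 2-cell-specific genes, whose mean was higher at an exact permutation p of 0.0571, which does not decide. A candidate biological explanation is that Med13 morpholino embryos lag on a course along which pools of 1 group also differ. Across 11676 genes outside the list, which are not independent replicates, the treatment change correlated with the contrast of the extreme pools at Pearson r = 0.19 within scrambled and 0.31 within Med13 morpholino libraries. The pools were scrambled replicates 1 and 2 and Med13 morpholino replicates 1 and 3. Scrambled replicate 2 stood apart on component 2, and Med13 morpholino replicate 1 lay farthest out on component 1. Each r may therefore describe 1 library rather than a shared course. The contrasts share libraries with the treatment change, and 50 simulations of unchanged, independent genes gave a mean r of -0.001 and a highest absolute r of 0.043 and 0.036; real genes vary together, so chance values spread wider than that. The test asked for at least 0.3 in both groups, which the scrambled libraries missed and the Med13 morpholino libraries met, and for under 0.1 in either to rule the lag out, which neither gave, so this too is open.

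The lower translation, ribosome biogenesis and splicing lists, the second pattern, may rest in part on single libraries. Without Med13 morpholino replicate 1, 0 of the 3 lists was called and their median log2 fold changes went from -0.296, -0.204 and -0.224 to -0.165, -0.078 and -0.099, so the medians shrank and stayed below 0. Protein-coding genes had a median of -0.058 in the main fit. Without Med13 morpholino replicate 4 all 3 lists were called, with medians of -0.396, -0.317 and -0.317 (camera adjusted p = 0.000279, 0.00071 and 0.000891). The Med13 morpholino libraries differed by degrees. Mean deviations in replicates 1 to 4 were -0.505, -0.188, -0.033 and 0.179 for translation factors. For housekeeping genes they were -0.182, -0.01, 0.008 and 0.255. With GC and length trends removed 3 of the 3 were called, which argues against such a trend as the whole cause. Whether the Med13 morpholino collections differed in handling or in their response to the morpholino is not known from these data. No biological explanation was tested.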

How the results depend on the processing

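Counted per setting, most named genes and lists kept their direction and their side of the threshold under the planned and added alternatives. The 2010 calls as a whole held less well in some settings. With no filter 849 of them held, and without Med13 morpholino replicate 2, 947 of the 1986 still tested. Under the 3 scalings 1836, 1897 and 1918 held. Of the calls, 0 changed sign under any scaling, 9 with protein-coding transcripts only, 3 with the main transcript only and 3 with voom. The number of changed genes was 1012 with no filter (623 higher, 389 lower), 1137 at a mean FPKM of at least 5 (576 and 561), where fewer genes were tested, 4336 with sample weights (1712 and 2624) and 3315 with transcripts kept apart (1721 and 1594); the lower genes were 1504 at an adjusted p below 0.1. Leaving out 1 library at a time gave 956 to 2404 changed genes, 608 to 1086 higher and 348 to 1353 lower, with fewer samples in each fit. The share of calls that were higher, 54.3% in the report, was 47.7% with equal summed FPKM, 39.5% with sample weights, 49.9% at an adjusted p below 0.1, and 43.7% to 63.6% with 1 library left out; the cause was not tested. The gap between mean correlations within and between groups was 0.0144 with no filter and 0.0631 at a mean of at least 5. The Med13 log2 difference, 0.034 in the main fit, was -0.025 with sample weights, 0.112 with quantile normalization, 0.22 with GC and length trends removed, and -0.001 to 0.101 with 1 library left out. Lists called numbered 3 with quantile normalization, 2 with the main transcript only, 8 with realigned rows (1 of them the mitochondrial list, which the main fit could not test), 0 with an estimated correlation, 1 with fry, and 2 to 6 with 1 library left out. Camera gained a call in some settings for mitotic (0.00755 with no filter), nuclear transport (0.0205 with no filter), unfolded protein response (0.0412 at a mean of at least 5), Obox (0.0444 with realigned rows) and cytosolic ribosomal genes (0.0193 with GC and length trends removed), as adjusted p. Genes near 0 that changed sign without a call were Med12 (0.026 with median-ratio scaling, 0.033 with protein-coding transcripts), Stat2 (0.004 with median-ratio scaling), Rplp2 (-0.033 with quantile normalization), Amhr2 (-0.065), Ldhc (-0.049) and Dppa3 (0.006) with sample weights, and Serpine2 (0.045 with the main transcript, 0.05 with voom). With 1 library left out, ranges that crossed 0 were -0.136 to 0.074 for Med12, -0.181 to 0.065 for Stat2, -0.075 to 0.174 for Amhr2, -0.181 to 0.09 for Dppa3 and -0.023 to 0.394 for Ldhc. Among called genes that the text names, Cflar changed sign with protein-coding transcripts only (-0.559). Of 112 named genes that were called, 74 kept the call in each fit that left out 1 library and 38 lost it in at least 1. Counted per gene and setting, 85 calls were lost and 14 gained (Cdk8 and Odf2) with all libraries kept or rows realigned, and 123 were lost with 1 library left out. Lists were not run with voom or sample weights, and neither lists nor named genes with transcripts kept apart. The consecutive title numbers were not taken to pair the samples, since the labels do not say that they do. The correlations of same-pair deviations were 0.38, 0.14, 0.01 and 0.19. Med13 morpholino replicates 1 and 2 matched their own number best and replicates 3 and 4 did not, so whether the numbers pair collections stays open. A replicate block gave 2620 changed genes against 2010, and either Cdk8 or Odf2 gained its call there. The library totals limit low genes. Changes of 0.5 on the log2 scale were mostly missed in simulated data with 200 changed genes, a rate that does not carry over to a comparison with 2010 calls.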

Other observations

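The test of shifted columns and those on realigned rows were chosen after the result was seen, and the test of retained introns before. Some mitochondrially encoded transcripts, which stand in the rows moved by 1 column, were lower after Med13 morpholino once realigned in the 7 libraries that have a value (4 scrambled, 3 Med13 morpholino). Of 13 protein-coding mitochondrial genes, 6 fell by limma over all genes of that fit and 0 rose, all 13 had a lower mean, and the median log2 fold change was -0.55. The missing library, Med13 morpholino replicate 4, lay nearest the scrambled libraries on component 1 (10.8). Leaving it out of the main fit moved the median of cytosolic ribosomal proteins from -0.127 to -0.287. The mitochondrial falls may therefore be larger here than with all libraries. The fixed list of mitochondrially encoded genes, with 15 members tested in that fit, was called lower by camera with the preset correlation (adjusted p = 0.00575), and not with an estimated correlation (0.887) or by fry (0.0535). The complex I subunit genes mt-Nd2 and mt-Nd4l went from 1462 ± 391 to 629 ± 119 FPKM and from 1614 ± 301 to 782 ± 30.9 FPKM (SD, n = 4 and 3; log2 fold changes -1.19 ± 0.23 and -1.02 ± 0.18 SE, limma adjusted p = 0.00566 and 0.00416). mt-Nd3 (-1.05), mt-Nd4 (-0.81), mt-Nd5 (-0.64) and mt-Atp8 (-0.66) also fell. The cytochrome oxidase genes mt-Co1 and mt-Co3 had log2 fold changes of -0.19 and -0.01 (limma adjusted p = 0.575 and 0.973), and the ribosomal RNAs mt-Rnr1 and mt-Rnr2 of -0.05 and 0.00 (adjusted p = 0.843 and 0.998). Wrong columns are an unlikely source of this difference: 3232 low values matched the library on the left and 0 that of their own column.

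The share of changed genes varied between classes of genes outside the fixed lists. Of 397 long intergenic noncoding RNAs tested, 79 were higher and 30 lower, a changed share of 27.5% against 16.7% of 9455 protein-coding genes. Of 102 unprocessed pseudogenes, 30 were higher and 14 lower (43.1%), 16 of them higher by at least 2-fold, and such copies can share reads with their parent genes. The share was 11.7% of 607 processed pseudogenes, 11.5% of 61 transcribed processed pseudogenes, 12.3% of 138 processed transcripts, 16.3% of 294 microRNA genes, 17.2% of 58 small nucleolar RNA genes, 19.2% of 286 antisense genes, 19.8% of 172 genes whose annotation is still to be tested by experiment and 16.7% of 54 symbols without a biotype. On the X chromosome 58 of 448 genes were higher and 40 lower (21.9%), against 16.9% changed on the autosomes. These shares were not tested against each other.

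A hypothesis fixed before its test was that Med13 morpholino embryos hold less unspliced RNA, given the role of Mediator in transcription. In 1454 genes with both kinds of transcript at a mean FPKM of at least 1, the mean log2 ratio of transcripts annotated with a retained intron to protein-coding transcripts was -1.19 ± 0.04 in scrambled and -1.22 ± 0.02 in Med13 morpholino libraries (SD, n = 4 each). The difference of -0.024 (exact permutation p = 0.257, two-sided) did not decide the matter, since such transcripts share exons with coding ones and the ratio may hide a change in introns.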
